A study of Homo sapiens with 6 samples.

How the data were processed

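RNA sequencing was performed on total RNA of MDA-MB-231 cells given a control siRNA or siRNA-1 against ERBBride, with 3 biological replicates per group per the labels. Libraries were made with the NEBNext Ultra RNA kit per the labels. The deposited file gives raw counts per Ensembl gene for the 6 libraries, made by the authors with HTSeq. The processing notes of the submitters also name Trimmomatic, STAR and kallisto, without versions, and the genome build hg38 (GRCh38). The annotation release, the strand setting of the counting, the part played by kallisto and any filter are not given in the sources used here.

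The table held 20042 genes. All were matched to a symbol by Ensembl identifier, 19552 with the same identifier version, and 19847 had a position in GENCODE release 29. In that release 19730 were protein coding and 19 were of a long non-coding type, while 195 were not listed. No gene was named ERBBride, and long non-coding RNA was therefore not analysed here beyond those 19 genes. Total counts ranged from 12813706 to 15014434 per library, and 3806 genes had 0 counts in all libraries. A floor of 3 counts corresponded to at most 0.234 CPM. The 10 genes with the most counts held 5.04% ± 0.218 of the counts in siCTRL and 3.99% ± 0.0536 in siRNA-1 libraries (SD, n = 3).

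Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which kept 12440 genes and 99.9% of counts and removed 7602 genes. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.972 to 1.02. The comparison of siRNA-1 with siCTRL used the quasi-likelihood F test with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.0656. The SE of a log2 fold change was derived from the fold change and its F statistic. A further count took genes with an absolute log2 fold change of at least 1. Principal components were computed from log2 CPM with a prior count of 2.

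The tests of genes and of lists, the gene lists and the rule for named genes were chosen before the data were examined. The 28 lists held 807 distinct genes, of which 26 had no entry in the table: ERBB receptors and ligands, EGFR and MAPK output, EGFR endocytosis and degradation, cytosolic chaperones, ER unfolded protein response, integrated stress response, proteasome subunits, autophagy and lysosome, DNA replication and E2F, G2/M and mitosis, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammatory, mesenchymal and EMT, epithelial, YAP and TEAD targets, TGF-beta and SMAD targets, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, NRF2 targets, ribosomal proteins, mitochondrially encoded, nuclear and histone RNA, haematopoietic cells, endothelial cells and luminal breast. Lists with at least 5 tested members were compared with the other genes by camera of limma 3.58.1 with a preset correlation of 0.01, two-sided and adjusted over the 28 lists. Changed members were counted with the adjustment over all genes tested and with that over the list alone. Named genes were EGFR and the ERBB receptor genes whatever their result. They were joined by the 8 largest rises and 8 largest falls among changed genes with a mean log2 CPM of at least 1 and groups that did not overlap. They also included the 3 members with the smallest adjusted p of each called list, and 1 of each other list where it had changed. The rule gave 73 entries, some of which are not reported, and other genes named in the text were chosen after their values were seen.

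Alternatives replaced 1 choice at a time. They were the size factors of DESeq2 1.42.0, no scaling beyond library size, no filter on low counts, a mean of at least 100 counts, the DESeq2 Wald test, limma-voom, the replicate number as a block, leaving out each library in turn and a threshold of 0.01. For lists they also included an estimated correlation and the rotation test fry. A correction of each library for GC content and transcript length (loess, span 0.4) was added after seeing the data. The same steps were tested on simulated counts with the dispersions of these libraries. The test recovered 29.9% of genes changed 1.25-fold, 76.1% at 1.5-fold and 87.7% at 2-fold, and 1.91% of calls were false. Apart from a planted list, 66 or 67 genes were changed at each fold among 12358 tested, while 62.5% of genes changed in the data. The adjustment is stricter where few genes change, so these shares do not give the recovery in the real comparison. A list planted in the simulation was called, and 0 other lists were. Genes were simulated independently of one another, so this does not show whether list calls hold where members are correlated.

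Sequences of 7 bases were counted in the 3' UTRs of GENCODE 29 for the 12121 tested genes with at least 50 bases of 3' UTR. Each of 15738 7-mers was tested for presence in genes that fell at least 2-fold, and separately in those that rose at least 2-fold, by a linear model with UTR length and GC content and a Bonferroni correction. This used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Isoforms, splicing and sequence variants were left out because the file holds gene counts alone, and protein levels were not measured in these samples.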

Results

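RNA sequencing measured the read count of each gene in 6 cultures of MDA-MB-231, an established human breast cancer cell line. A small interfering RNA (siRNA) is a short RNA duplex that guides the breakdown of transcripts matching it. In 3 cultures the cells received a control siRNA (siCTRL), and in the other 3 they received siRNA-1, directed against ERBBride. The labels call the 3 cultures of each group biological replicates, and how they were separated is not given in the sources used here, so that each p-value measures the spread between these samples. Total counts per library were 14847527, 12813706 and 13853510 in siCTRL 1 to 3, and 14153969, 15014434 and 14385650 in siRNA-1 replicates 1 to 3. Between 14663 and 14857 genes had a count in a library. A count of 3 corresponded to at most 0.234 CPM (counts-per-million) in any library, and such limits cover counting error only. Levels are CPM normalised by the trimmed mean of M values, as mean ± SD with n = 3 per group, and fold changes compare siRNA-1 with siCTRL.

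The series title names the stability of EGFR, the fitness of cells and a long non-coding RNA (lncRNA), a transcript that is not translated into protein. The comparison asks which transcripts differed in cells that received the siRNA against ERBBride. The count table had no entry named ERBBride, so its level was not analysed here and its knockdown could not be checked. EGFR, the receptor for epidermal growth factor, fell 1.27-fold, from 459 ± 17.9 to 360 ± 15.2 CPM (log2 fold change -0.35, SE 0.054, adjusted p = 0.000147, edgeR). The related receptor gene ERBB2 fell 1.21-fold, from 79.6 ± 0.524 to 65.9 ± 3.27 CPM (adjusted p = 0.00181). ERBB3 fell 1.58-fold, from 7.79 ± 0.500 to 4.92 ± 0.408 CPM (adjusted p = 0.00147). ERBB4 had 1 to 4 counts in each library and was not tested. On the GRCh38 assembly, EGFR (ENSG00000146648) is annotated on the plus strand of chromosome 7 from 55019021 to 55211628. ERBB2 (ENSG00000141736) lies on chromosome 17 from 39687914 to 39730426 and ERBB3 (ENSG00000065361) on chromosome 12 from 56076799 to 56103505, both on the plus strand. All 3 are protein-coding genes, and the values are RNA levels that say nothing of protein.

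Across the transcriptome, 7772 of the 12440 genes tested changed (62.5%), with 3921 higher and 3851 lower in siRNA-1 cells. Most of these changes were small: 6515 of the changed genes (83.8%) moved by less than 2-fold, and the median absolute log2 fold change of changed genes was 0.51. Among genes that changed at least 2-fold, falls were in the majority, with 1012 falls and 245 rises. The groups did not overlap at 8405 genes (67.6%), where chance gives 10%. The libraries separated by group along the first principal component, which held 80.8% of the variance. Along the second component (8.43%), siCTRL 2 lay at -22.3 and the other libraries between -2.90 and 13.3. The log2 difference of siCTRL 2 from the mean of the other controls had an SD of 0.230 over 9884 genes, against 0.128 between those other controls. Without siCTRL 2, 8635 genes changed (4329 rose and 4306 fell) and 1359 changed at least 2-fold (307 rose and 1052 fell), an alternative that was planned. At a mean of 100 counts or more, fewer low-count genes were tested and 731 genes changed at least 2-fold.

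The gene with the smallest p was KPNB1, which encodes importin beta, a carrier of proteins into the nucleus. KPNB1 fell 8.17-fold, from 593 ± 21.0 to 72.5 ± 1.33 CPM (log2 fold change -3.03, SE 0.056, adjusted p = 2.4e-11, edgeR). KPNB1 (ENSG00000108424) lies on the plus strand of chromosome 17 from 47649476 to 47685505, and the antisense gene AC015674.1 overlaps 3.48% of its exonic bases. The strand setting of the counting is not given in the sources used here. Among changed genes with a mean log2 CPM of at least 1 and groups that did not overlap, the largest falls were those of PHGDH, the enzyme that opens serine synthesis, which fell 16.4-fold from 15.1 ± 3.97 to 0.905 ± 0.197 CPM, and ATP6V0D2, a subunit of the vacuolar proton pump, which fell 12.3-fold. They were followed by RAB37 (11.9-fold), FCF1, a factor of ribosome assembly (10.5-fold), the cytochrome P450 gene CYP2S1 (8.28-fold), the sorting nexin gene SNX10 (8.26-fold), KPNB1 and the adhesion gene AMIGO2 (8.03-fold). The largest rises among the same genes were those of ID3, an inhibitor of helix-loop-helix transcription factors, which rose 20.3-fold from 0.837 ± 0.425 to 17.5 ± 1.92 CPM, and of the transcription factor gene ATOH8, which rose 13.8-fold from 0.372 ± 0.149 to 5.16 ± 0.618 CPM. CYP4F11 (8.80-fold), the cytokine gene IL24 (8.60-fold), the cholesterol hydroxylase gene CH25H (6.83-fold), the antiviral gene RSAD2 (6.50-fold) and the cytokine receptor genes IL7R (6.20-fold) and IL6R (6.01-fold) followed. The highest adjusted p among these 16 genes was 1.3e-05, and in each of them all siRNA-1 libraries lay on one side of all control libraries. The 7-base sequence GCTCACT was present in the 3' untranslated region (UTR) of 5 of these 8 falls and in 0 of these 8 rises. It was picked as the sequence most enriched in genes that fell at least 2-fold (34.4% against 14.9% of the others). That set holds these falls, so the contrast is not separate evidence.

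Of 28 gene lists fixed before the data were examined, 14 differed from the other genes by a list test (limma camera, adjusted p under 0.05), 6 upwards and 8 downwards. The lists held 686 tested members, of which 481 changed. With the correlation between members estimated from the data, 0 lists were called by camera, 3 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0819. The rotation test fry called 20, though it does not compare a list with other genes. Counts adjusted over the list alone were equal to those over all genes tested except where given. Members named beyond the fixed rule for named genes were chosen after their values were seen.

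**Figure D1:**
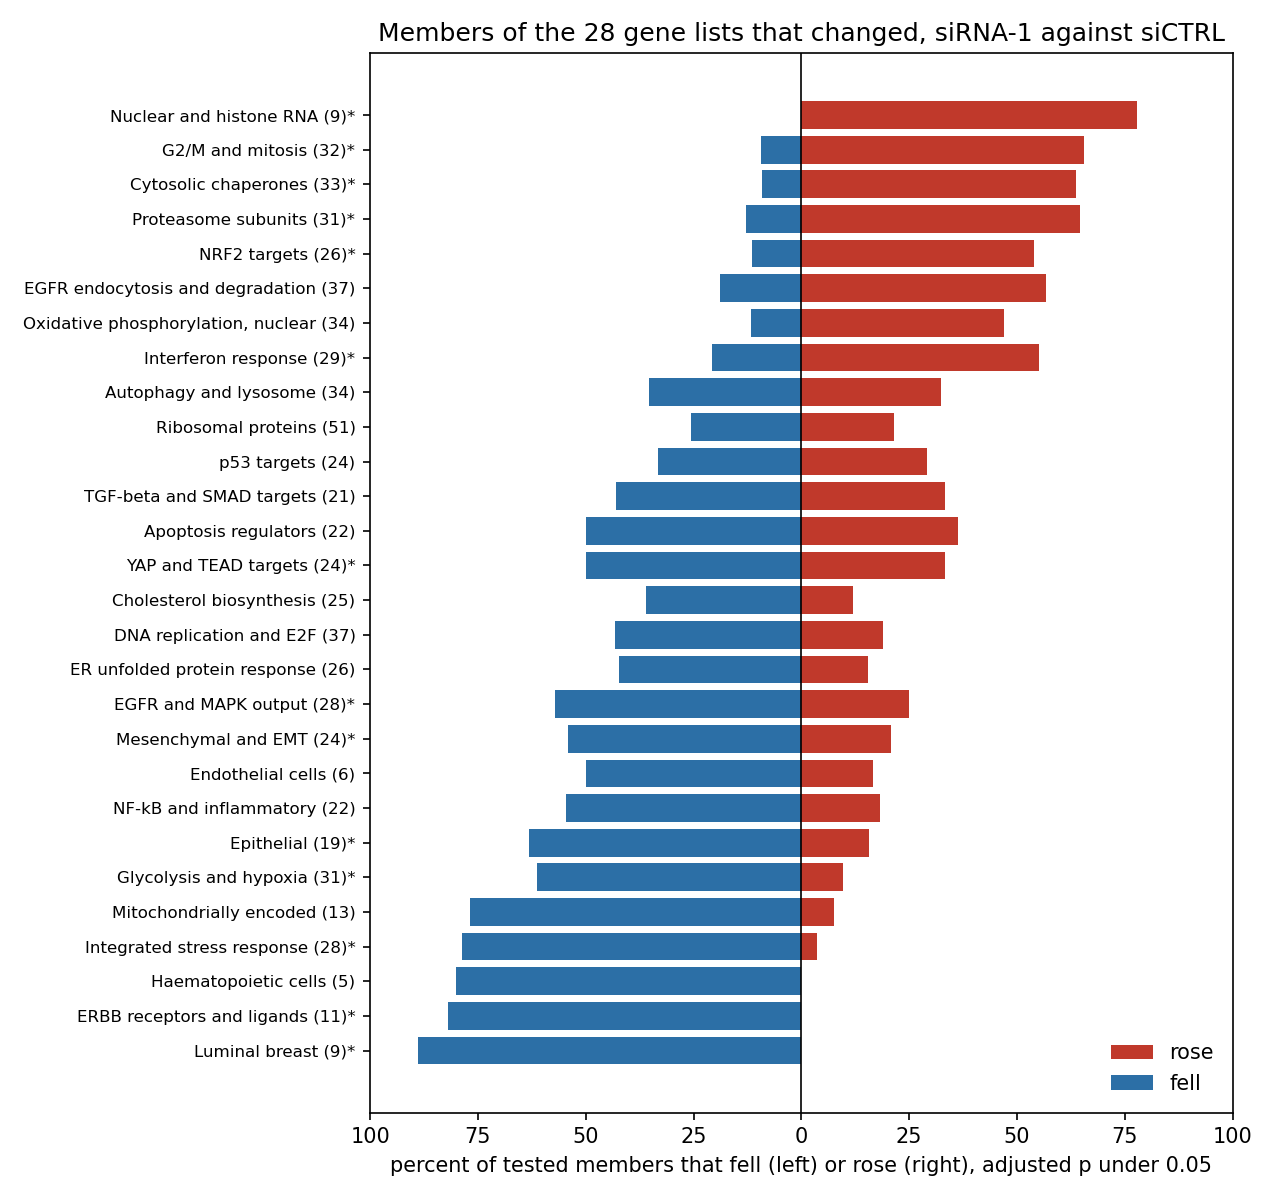
Horizontal bars give the percent of tested members of each of 28 gene lists that fell (left) or rose (right) in siRNA-1 cells against siCTRL (n = 3 each, adjusted p under 0.05, edgeR), with the number of tested members in parentheses and an asterisk where the list test called the list. Of 28 integrated stress response genes 22 fell and 1 rose, and of 32 G2/M genes 21 rose and 3 fell.

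ERBB receptors and their ligands fell together: 9 of 11 tested members fell and 0 rose, with a median log2 fold change of -0.44. The list was called downwards (adjusted p = 0.0210, and adjusted p = 0.349 with an estimated correlation). The ligand genes AREG (amphiregulin) and EREG (epiregulin) fell 1.91-fold, from 165 ± 15.4 to 86.3 ± 2.66 CPM, and 2.35-fold, from 35.1 ± 3.72 to 14.9 ± 0.719 CPM. BTC (betacellulin) fell 2.30-fold, while HBEGF (log2 fold change -0.04, adjusted p = 0.655) and NRG2 (-0.04, adjusted p = 0.878) did not pass the test. Of 28 genes that respond to EGFR and MAPK signalling, 16 fell, 7 rose and 5 did not pass, and adjusted over the list alone 17 fell and 7 rose. PLAU, the urokinase gene, fell 3.08-fold from 613 ± 54.4 to 199 ± 1.08 CPM, the early response gene IER3 fell 2.19-fold, and DUSP6, a phosphatase that acts on ERK, fell 2.60-fold from 356 ± 44.3 to 137 ± 5.98 CPM. Members that rose included the transcription factor genes JUNB (1.73-fold) and FOSB (3.17-fold). This list was called downwards (adjusted p = 0.00654, and adjusted p = 0.349 with an estimated correlation).

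**Figure D2:**
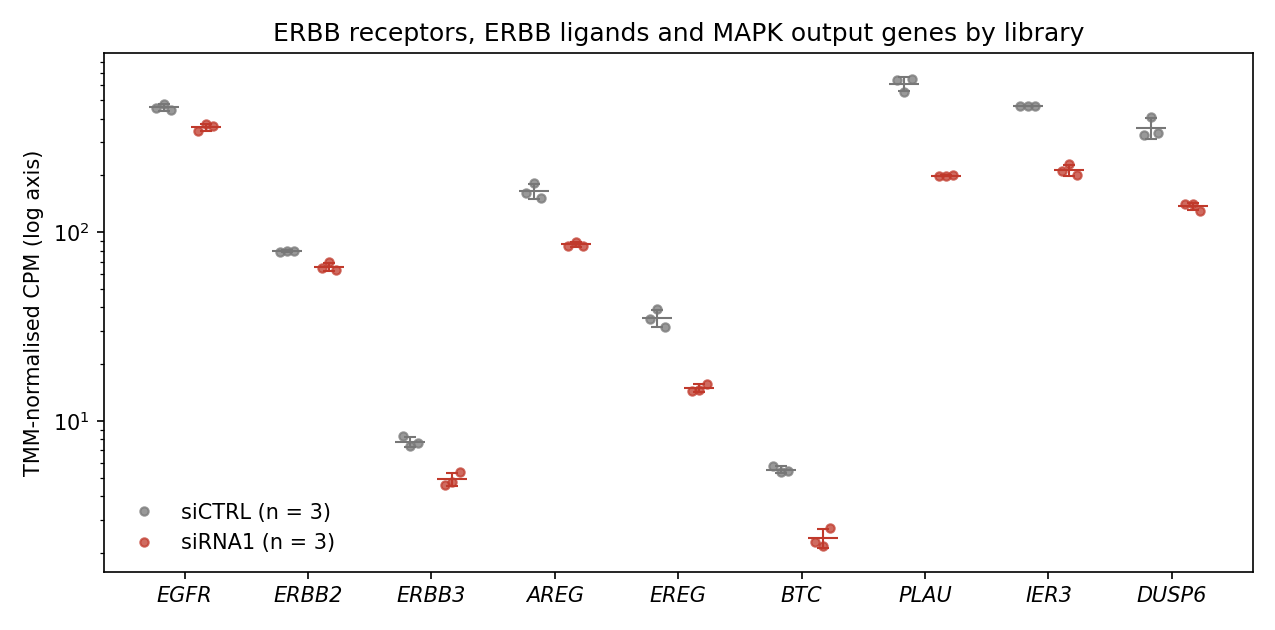
Points are the libraries of siCTRL (grey, n = 3) and siRNA-1 (red, n = 3) for 3 ERBB receptor genes, 3 ligand genes and 3 MAPK output genes, on a log axis of normalised CPM, and bars show mean ± SD. All siRNA-1 points lie below all siCTRL points for each gene, from EGFR (459 to 360 CPM) to PLAU (613 to 199 CPM).

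Genes of EGFR endocytosis and degradation moved in both directions: 21 of 37 rose, 7 fell and 9 did not pass. The list was not called (adjusted p = 0.572, and adjusted p = 0.827 with an estimated correlation). ERRFI1, which encodes an inhibitor of the EGFR kinase, fell 3.61-fold from 583 ± 27.4 to 162 ± 9.55 CPM (adjusted p = 1.1e-09). LRIG1, a negative regulator of ERBB receptors, fell by 1.61 on the log2 scale, whereas the ubiquitin ligase genes CBL (log2 fold change 0.26) and CBLB (0.41) rose.

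Cytosolic chaperone genes rose as a group, with 21 of 33 higher and 3 lower (median log2 fold change 0.28, adjusted p = 0.00579, and adjusted p = 0.349 with an estimated correlation). DNAJB4 rose 2.33-fold from 27.5 ± 2.46 to 64.0 ± 0.369 CPM, and the HSP90 cochaperone gene FKBP4 rose 1.64-fold. Against this direction, the HSP70 cochaperone gene DNAJA1 fell 3.95-fold from 388 ± 24.1 to 98.3 ± 3.73 CPM, and HSP90AB1 (log2 fold change -0.31) and HSPD1 (-0.15) fell too. HSPA1B rose (0.48) while HSPA1A did not pass (0.11), and reads of these near-identical genes cannot be assigned with certainty. Among proteasome subunits 20 of 31 rose, 4 fell and 7 did not pass, and adjusted over the list alone 21 rose. PSMC6 (1.44-fold), PSMA3 (1.37-fold) and PSMD8 (1.35-fold) were among the rises, and PSMD2 (log2 fold change -0.54), PSMB5 (-0.46), PSMD3 (-0.40) and PSMC2 (-0.19) fell. The proteasome call (adjusted p = 0.0338, and adjusted p = 0.612 with an estimated correlation) was lost without siCTRL 2 (0.0837), at a mean of 100 counts or more (0.0681) and after a correction for GC content and length chosen after seeing the data (0.0541), within a range of 0.0204 to 0.612 by camera over all settings run. The median log2 fold change of the list was 0.25 with all libraries, 0.18 without siCTRL 2 and 0.23 after the correction. Members of this list lay 0.11 lower on the log2 scale in siCTRL 2 than in the other controls (median -0.11).

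The integrated stress response, a programme that slows translation and induces amino acid supply genes through ATF4, fell as a group, with 22 of 28 members lower and 1 higher. Adjusted over the list alone, 23 fell and 1 rose. The median log2 fold change was -0.80 (adjusted p = 1.6e-11, and adjusted p = 0.349 with an estimated correlation). TRIB3, a pseudokinase gene induced by stress, fell 4.01-fold from 89.0 ± 2.64 to 22.2 ± 1.59 CPM, the cystine transporter gene SLC7A11 fell 2.72-fold and CHAC1, an enzyme that degrades glutathione, fell 4.21-fold. ATF4 itself fell (log2 fold change -0.63), as did the asparagine synthetase gene ASNS (-2.42), and ATF5 was the 1 member that rose (1.15). DDIT3 (0.01, adjusted p = 0.961), ATF3 (-0.09, adjusted p = 0.409), PPP1R15A (0.06), CEBPB (-0.19) and STC2 (-0.85) did not pass. Of the 22 members that fell, 7 carried GCTCACT in the 3' UTR (31.8%), against 16.5% of the other tested genes, whatever their direction. Of all 28 members 7 carried it. Among all genes that fell at least 2-fold the share was 34.4%, so the share in these members is not particular to the list. This sequence was picked from falls in these same data. Genes of the unfolded protein response of the endoplasmic reticulum were not called (adjusted p = 0.242, and adjusted p = 0.827 with an estimated correlation), with 4 of 26 higher and 11 lower. SEC24D, a coat protein gene of transport vesicles, rose 2.35-fold, and the chaperone genes HSPA5 (log2 fold change -1.09) and HYOU1 (-1.28) fell. Without siCTRL 2, in which the list lay lower than in the other controls (median -0.20), 17 of these genes fell and the list was called (adjusted p = 0.0197, within a range of 0.0197 to 0.827 by camera over all settings run). Autophagy and lysosome genes were not called (adjusted p = 0.768, and adjusted p = 0.927 with an estimated correlation): 11 of 34 rose and 12 fell, and adjusted over the list alone 13 fell. Their median log2 fold change was -0.04 although the list test pointed upwards, and both rested on single libraries: without siCTRL 2 the test pointed downwards (median -0.11, 12 higher and 17 lower), and without siCTRL 3 the median was 0.015.

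Mitotic genes were higher and genes of DNA replication moved both ways. In the list of G2/M and mitosis 21 of 32 rose and 3 fell (median log2 fold change 0.43, adjusted p = 0.00174, and adjusted p = 0.612 with an estimated correlation). BIRC5, a subunit of the chromosomal passenger complex, rose 1.66-fold from 121 ± 2.25 to 201 ± 5.76 CPM, the cyclin gene CCNA2 rose 1.48-fold and the mitotic kinase gene PLK1 rose 1.68-fold. The kinesin gene KIF11 (log2 fold change -0.69), the checkpoint kinase gene BUB1 (-0.65) and HMMR (-0.89) fell. The list lay higher in siCTRL 2 than in the other controls (median 0.33), and without siCTRL 2, 28 of the members rose and 3 fell. In the list of DNA replication and E2F targets 16 of 37 fell and 7 rose (adjusted p = 0.0697, and adjusted p = 0.588 with an estimated correlation). CHEK1, a kinase of the replication checkpoint, fell 1.85-fold from 93.1 ± 1.45 to 50.4 ± 1.90 CPM, and the polymerase gene POLA1 fell by 1.06 on the log2 scale.

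**Figure D3:**
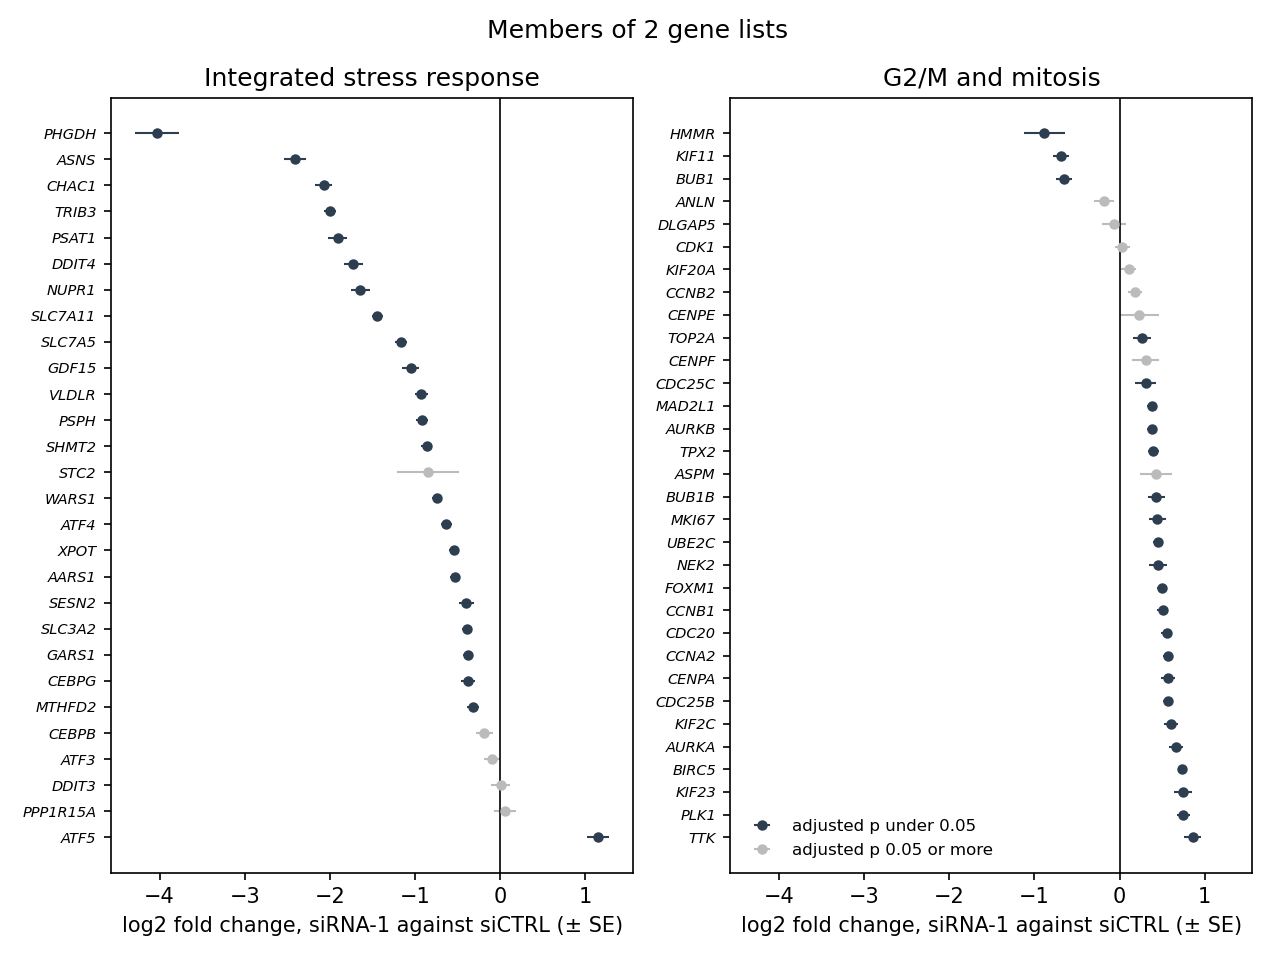
Points are log2 fold changes of siRNA-1 against siCTRL (n = 3 each) with bars of ± SE for members of the integrated stress response list (left) and of the G2/M and mitosis list (right), dark where the adjusted p was under 0.05. PHGDH (-4.03) and TRIB3 (-2.00) lie far to the left and ATF5 (1.15) to the right, while mitotic members reach from HMMR (-0.89) to TTK (0.86).

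Lists of cell death and p53 targets were not called and their members split. Among p53 targets 7 of 24 rose and 8 fell (adjusted p = 0.733, and adjusted p = 0.827 with an estimated correlation). The death receptor gene TNFRSF10B fell 2.59-fold from 165 ± 19.3 to 63.8 ± 2.59 CPM, and CDKN1A, the gene of the cell cycle inhibitor p21, did not pass (log2 fold change -0.12, adjusted p = 0.157). Among apoptosis regulators 8 of 22 rose and 11 fell (adjusted p = 0.308, and adjusted p = 0.555 with an estimated correlation). BAD, which promotes apoptosis, fell 3.72-fold from 61.2 ± 3.61 to 16.4 ± 1.11 CPM, and the proapoptotic genes BID (log2 fold change 1.14) and BAK1 (0.88) rose.

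Interferon response genes were higher on balance: 16 of 29 rose, 6 fell and 7 did not pass (median log2 fold change 0.35, adjusted p = 0.0149, and adjusted p = 0.349 with an estimated correlation). RSAD2 rose 6.50-fold, OASL rose 3.38-fold from 21.9 ± 0.695 to 74.0 ± 2.71 CPM and the ISG15 ligase gene HERC5 rose 2.09-fold. Falls in the same list included the apoptosis gene XAF1 (log2 fold change -2.42) and the transcription factor genes IRF1 (-0.84) and STAT2 (-0.82). NF-kB and inflammatory genes were not called (adjusted p = 0.295, and adjusted p = 0.827 with an estimated correlation), with 4 of 22 higher and 12 lower. In that list the signalling adaptor gene TRAF1 fell 1.72-fold, and members lay higher in siCTRL 2 than in the other controls (median 0.46).

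Genes of cell state mostly fell, whether mesenchymal or epithelial. In the mesenchymal list 13 of 24 fell and 5 rose (median log2 fold change -0.33, adjusted p = 0.00839, and adjusted p = 0.349 with an estimated correlation). The matrix gene TGFBI fell 2.60-fold, while the collagen gene COL5A1 rose 2.04-fold. In the epithelial list 12 of 19 tested members fell and 3 rose (median log2 fold change -0.56, adjusted p = 0.00654, and adjusted p = 0.349 with an estimated correlation). This list held 26 genes, and GRHL2 (2 counts over all libraries) and ESRP1 (10) were among those with too few counts to test. The keratin genes KRT7 (2.18-fold) and KRT19 (1.59-fold) and the junction gene CLDN7 (2.57-fold) fell, and the keratin gene KRT17 rose (log2 fold change 2.92) from 0.218 ± 0.0638 CPM in siCTRL, a level near 3 counts per library. Keratin genes share sequence with one another, so their reads are assigned with some uncertainty. Luminal breast genes fell at 8 of 9 tested members with 0 rises (median log2 fold change -1.34, adjusted p = 0.00579, and adjusted p = 0.349 with an estimated correlation). The list held 15 genes. Too few counts to test over all libraries were found for ESR1 (6), FOXA1 (3), TFF1 (34), PGR (0), PIP (0) and SCGB2A2 (0). The falls therefore concern the measured members alone. AGR2 fell 2.59-fold from 42.8 ± 4.49 to 16.6 ± 1.75 CPM, the transcription factor gene SPDEF fell 3.18-fold and KRT18 fell 1.47-fold. KRT18, KRT8 and XBP1 stand in this list and in another one, and 5 genes stood in more than 1 list.

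Targets of YAP and TEAD, transcriptional regulators of cell contact and growth, fell at 12 of 24 members and rose at 8 (median log2 fold change -0.25, adjusted p = 0.0169, and adjusted p = 0.349 with an estimated correlation). CCN2, a matrix signalling gene, fell 3.82-fold from 328 ± 36.6 to 85.9 ± 3.00 CPM, the receptor kinase gene AXL fell 2.24-fold from 1219 ± 23.3 to 544 ± 21.1 CPM and the growth factor gene TGFB2 fell 2.72-fold. Members that rose included the kinase gene LATS2 (log2 fold change 0.99), which restrains YAP. TGF-beta and SMAD targets were not called (adjusted p = 0.701, and adjusted p = 0.854 with an estimated correlation), with 7 of 21 higher and 9 lower. Their median log2 fold change was -0.02 and their mean 0.10, while the list test pointed downwards. Without 1 library the median was -0.03 (siCTRL 1), -0.08 (siCTRL 2) and -0.15 (siCTRL 3). For siRNA-1 replicates 1, 2 and 3 left out in turn it was -0.02, -0.05 and -0.09, and the test pointed upwards without siRNA-1 replicate 1. The receptor gene TGFBR1 fell 2.96-fold from 252 ± 9.96 to 85.3 ± 0.634 CPM.

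Glycolysis and hypoxia genes fell at 19 of 31 members and rose at 3 (median log2 fold change -0.43, adjusted p = 1.9e-07, and adjusted p = 0.0819 with an estimated correlation). BNIP3L, a receptor for mitophagy, fell 6.47-fold from 172 ± 12.2 to 26.5 ± 1.91 CPM, the glucose transporter gene SLC2A3 fell 4.32-fold and the phosphofructokinase gene PFKL fell 3.48-fold. Cholesterol synthesis genes were not called (adjusted p = 0.240, and adjusted p = 0.827 with an estimated correlation), with 3 of 25 higher and 9 lower. The sterol oxidase gene MSMO1 fell 5.07-fold from 224 ± 40.0 to 44.2 ± 3.67 CPM. These genes lay lower in siCTRL 2 than in the other controls (median -0.32), and without siCTRL 2, 19 fell and the list was called (adjusted p = 0.00666, within a range of 0.00666 to 0.827 by camera over all settings run). NRF2 targets, genes of the antioxidant response, rose at 14 of 26 members and fell at 3 (median log2 fold change 0.32, adjusted p = 0.0218, and adjusted p = 0.349 with an estimated correlation). The glutathione synthesis gene GCLM rose 1.77-fold and the reductase gene AKR1B10 rose 5.04-fold from 2.07 ± 0.188 to 10.5 ± 0.363 CPM, whereas SLC7A11, which this list shares with the stress response list, fell. This call was lost without siCTRL 2 (adjusted p = 0.0595) and at a mean of 100 counts or more (0.0849), within a range of 0.0152 to 0.349 by camera over all settings run. Without siCTRL 2 the median log2 fold change was 0.26, with 15 rises and 4 falls.

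Nuclear genes of oxidative phosphorylation rose at 16 of 34 members and fell at 4, and the list stood close to the threshold (adjusted p = 0.0523, and adjusted p = 0.827 with an estimated correlation). CYC1, the gene of cytochrome c1, rose 1.42-fold. Members of the list lay lower in siCTRL 2 than in the other controls (median -0.22). Their median log2 fold change was 0.21 with all libraries and 0.13 without siCTRL 2. The list was called without siCTRL 1 (adjusted p = 0.0239), without siCTRL 3 (0.0204) and without siRNA-1 replicate 3 (0.0342), and not without siCTRL 2 (0.164), siRNA-1 replicate 1 (0.0628) or siRNA-1 replicate 2 (0.0510), within a range of 0.0204 to 0.827 by camera over all settings run. Genes encoded in the mitochondrial genome fell at 10 of 13 members and rose at 1, and adjusted over the list alone, or without siCTRL 1 or siCTRL 2, 2 rose (adjusted p = 0.0697, and adjusted p = 0.662 with an estimated correlation). MT-CYB, the gene of cytochrome b, fell 1.53-fold from 3414 ± 135 to 2233 ± 20.2 CPM. The share of counts from mitochondrial genes was 3.84% ± 0.194 in siCTRL and 3.12% ± 0.0294 in siRNA-1 cells (SD, n = 3 each). Without siCTRL 2 the mitochondrial list was called (adjusted p = 0.00487, within a range of 0.00487 to 0.662 by camera over all settings run). Its members lay lower in siCTRL 2 than in the other controls (median -0.18), and lower in siCTRL 1 than in siCTRL 3 (median -0.14). Reads of nuclear copies of these genes cannot be separated. Ribosomal protein genes were not called (adjusted p = 0.930, and adjusted p = 0.985 with an estimated correlation), with 11 of 51 higher, 13 lower and 27 that did not pass. Adjusted over the list alone, 10 of them rose and 12 fell, and RPL14 fell 1.60-fold. These counts rested on single libraries: 21 fell without siCTRL 2, 8 without siCTRL 1, siCTRL 3 or siRNA-1 replicate 2, and 7 without siRNA-1 replicate 3, and 6 rose without siRNA-1 replicate 1.

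Histone genes, the measured part of a list of nuclear and histone RNA, rose at 7 of 9 members with 0 falls (median log2 fold change 0.83, adjusted p = 0.0223, and adjusted p = 0.566 with an estimated correlation). H2BC12 (1.64-fold), H1-2 (2.23-fold) and H2AC6 (1.86-fold) rose, and reads of near-identical histone genes are assigned with uncertainty. The list held 34 genes, 25 of them with an entry, and H1-3, H1-5 and H3C4 were among those with 0 counts over all libraries. A difference between the groups in the RNA that entered the libraries was not tested, so these values do not separate it from a rise in histone expression. The histone call was lost without siCTRL 2 (adjusted p = 0.0550, within a range of 0.0112 to 0.566 by camera over all settings run), in which these genes lay lower than in the other controls (median -0.30). Without it the median log2 fold change was 0.71, and 7 members rose and 0 fell. Most markers of other cell types had too few counts to test, and 5 of 25 haematopoietic and 6 of 16 endothelial markers were tested. Of the haematopoietic markers 4 fell and 0 rose (adjusted p = 0.0976, and adjusted p = 0.349 with an estimated correlation), with CD14 2.25-fold lower, from 17.3 ± 2.48 to 7.71 ± 0.450 CPM. Among the endothelial markers 3 fell and 1 rose (adjusted p = 0.135, and adjusted p = 0.349 with an estimated correlation), with ROBO4, a guidance receptor gene, 8.02-fold lower, from 49.1 ± 6.09 to 6.10 ± 0.343 CPM.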

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

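The correction for GC content and length was chosen after the results were seen, and the other alternatives were planned. The 73 named entries kept their direction and their side of the threshold in each alternative that tested them (1012 values). Most of them were chosen for a small adjusted p or a large change in these same libraries, so this stability follows in part from the choice. Changed genes numbered 7772, and from 6206 at a threshold of 0.01 to 8635 without siCTRL 2. All genes shared with the initial call kept their direction in every setting (7470 genes with the replicate block, which called 7535 genes). No pairing by replicate number was seen: deviations of same-number libraries correlated at 0.144, -0.0814 and -0.138 across 9884 genes, and those of other pairs at -0.198 to 0.217. Deviations were taken from the mean of each group of 3 and so depend on one another. The values therefore do not exclude a shared day or batch. At a mean of 100 counts or more, 731 genes changed at least 2-fold, 105 up and 626 down, since fewer genes were tested (10050), and the histone, haematopoietic and endothelial lists and some named genes gave no value there, nor did the haematopoietic list without siCTRL 1. With an estimated correlation, camera called 0 lists (14 with the preset correlation), with 3 at an unadjusted p under 0.05, and the cause was not tested. Leaving out 1 library gave 6848 to 8635 changed genes and 1273 to 1359 changed at least 2-fold. Proteasome and NRF2 calls were lost at a mean of 100 counts or more (0.0681 and 0.0849), and oxidative phosphorylation was called without scaling and with the block. By fry, which tests movement one way within a list, 20 lists passed, among them 6 that camera did not call. In simulated counts with the depth, spread and n of these samples, but far fewer changed genes, the smallest fold tried was recovered at 29.9%. That share is therefore not the recovery in the real comparison. Which of depth, spread and n limits the recovery was not tested. Depth leaves out weakly expressed genes, since genes with counts under about 10 in most libraries were not tested.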

Other observations

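The tests of other scalings, Alu repeats, the coincidence at KPNB1 and the splits of the samples, and the gene families in the first paragraphs, were chosen only after the results were seen. The 7-mer scan, the search for a duplex and the other tests at KPNB1 were not among the tests chosen before the data were examined either. They were aimed at patterns seen in these results. Integrin genes, which encode receptors for the cell matrix, mostly fell: 13 of 16 tested fell and 2 rose (median log2 fold change -0.49, camera adjusted p over 10 families = 0.00208, and adjusted p = 0.164 with an estimated correlation). ITGA3 fell 2.45-fold from 2731 ± 223 to 1115 ± 22.8 CPM (n = 3 each), ITGA6 fell 1.99-fold and ITGB3 fell 5.73-fold, while ITGA5 rose 1.51-fold. Genes of serine and one-carbon metabolism fell at 7 of 11 members and rose at 2 (adjusted p = 0.00547, and adjusted p = 0.641 with an estimated correlation), but 5 of the 7 (PHGDH, PSAT1, SHMT2, PSPH and MTHFD2) also stand in the integrated stress response list, so the family and its p are not separate evidence. Among the other members, MTHFD1L (2.42-fold lower) and SHMT1 (log2 fold change -0.26) fell.

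The other families were not called by camera and their members moved both ways. In polyamine metabolism, OAZ1, the antizyme that restrains ornithine decarboxylase, fell 7.72-fold from 387 ± 14.01 to 50.1 ± 1.38 CPM, and SAT1 (3.26-fold), SRM (1.77-fold) and ODC1 (1.56-fold) rose (6 of 13 rose, 5 fell, adjusted p = 0.664). Of 32 ubiquitin-conjugating enzyme genes 15 rose and 10 fell (adjusted p = 0.664), and UBE2D1 fell 7.08-fold from 44.8 ± 2.54 to 6.32 ± 0.841 CPM. In the BMP and ID family 6 of 15 rose and 3 fell (adjusted p = 0.191), with ID1 2.66-fold and ID4 2.38-fold higher. Subunits of the vacuolar proton pump rose at 13 of 19 members and fell at 5 (adjusted p = 0.254). Aminoacyl-tRNA synthetases fell at 13 of 20 members (adjusted p = 0.233). Among importins and exportins 11 of 23 rose and 11 fell (adjusted p = 0.429), among nucleoporins 13 of 30 rose and 7 fell (adjusted p = 0.664), and among collagens 10 of 25 rose and 10 fell (adjusted p = 0.664).

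More genes fell than rose at least 2-fold, at a ratio of 4.13. The ratio stayed at 3.21 (95% interval 2.81 to 3.66) at the lowest of the other scalings. After the GC and length correction it was 3.90 (3.39 to 4.48). These values argue against either as the whole source. The intervals in this paragraph treat genes as independent and leave out the spread between libraries. The ratio was 3.43 without siCTRL 2 and 5.96 at a mean of 100 counts or more. The 7-mer GCTCACT was in the 3' UTR of 34.4% of genes that fell at least 2-fold and of 14.9% of the others (Bonferroni p = 4.3e-54, n = 12121 genes, which are not independent replicates), and 6 of the next 9 7-mers overlapped it by 6 bases, while in genes that rose at least 2-fold CAACCGA (4.66% against 1.03%, Bonferroni p = 0.00167) and ATACGCT (5.08% against 1.32%, Bonferroni p = 0.00258) passed too. Alu repeats hold GCTCACT, the 7-mer of the falls, and they were sought only by an exact match to a short Alu sequence. Of 1236 genes with the 7-mer but without that Alu sequence, 19.98% fell at least 2-fold. The share was 6.44% of 10116 genes without the 7-mer, a ratio of 3.11 (2.72 to 3.55). Alu copies with that exact sequence are therefore not the whole source of the enrichment. Alu copies that lack it may be among the 1236 genes, so the test does not decide whether Alu repeats account for the enrichment. A candidate explanation, found and tested on the same data, is that a strand of siRNA-1 acted through its seed on transcripts with GCTCACT. Among genes without it the ratio was still 2.91 (2.50 to 3.38), so exact matches in a gene's own annotated 3' UTR are not the whole source. Of 618 genes with only a second enriched 7-mer (GTAAGCA, described below), 87 fell and 10 rose at least 2-fold. Of 9498 genes with neither, 564 fell and 214 rose. Effects through other genes and through partial sites were not tested, so seed action as the whole source is not decided. With a single siRNA, effects that follow from such sites and effects of the loss of ERBBride stay open together, and the sequence of siRNA-1 is not given in the sources used here.

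KPNB1 fell with the smallest p of all genes, and a further 7-mer unrelated to the first, GTAAGCA, was enriched in genes that fell (15.5% against 6.96%, Bonferroni p = 7.7e-16, n = 12121 genes). If GCTCACT and GTAAGCA were sites for both strands of a single 19-base duplex, a transcript matching it would hold TGCTTAC, any 3 bases and GCTCACT. TGCTTAC is the reverse complement of GTAAGCA. Of 16066 long non-coding genes 1 holds such a pair, the single-exon AC015674.1 (chromosome 17, 47682417 to 47682683, minus strand, TGCTTACTTAGCTCACT). However, 0.095 of random pairs matched at least as many genes, so this pair and a random one cannot be told apart by the number of genes. AC015674.1 lies antisense to the 3' UTR of KPNB1, whose transcripts hold the reverse complement AGTGAGCTAAGTAAGCA in 5 of 14 annotated cases (NR1I2 holds the pair on this strand too, with other middle bases), but all 267 bases of AC015674.1 lie over KPNB1 exons, which fixes this outcome, so it does not decide whether the siRNA duplex matches the KPNB1 transcript itself. None of 1000 random pairs stood in the 3' UTR of the gene with the smallest p (permutation p = 0.000999, the smallest they can give). Only 9.7% of them stood in any tested gene, and the test was chosen once KPNB1 was known to hold the pair. The test restates that observation and does not decide whether the match is a coincidence. Reads lost to the antisense gene would cover only 3.48% of KPNB1 exonic bases against 87.8% of its CPM lost. The hypothesis that siRNA-1 may act on KPNB1 directly, an effect of losing the antisense RNA on KPNB1, and whether AC015674.1 is ERBBride all stay open.

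Integrated stress response genes fell and G2/M genes rose. After the GC and length correction the smaller of the medians was 0.46 in absolute log2 fold change, and the 10 most abundant genes differed in their share of counts by only 1.04 percentage points between groups, which argues against both as the cause. Stress response members without GCTCACT in the 3' UTR had a median log2 fold change of -0.63 (21 genes) and those with it -1.64 (7 genes). Matches to this 7-mer in the members' own 3' UTRs are therefore not the whole cause of the fall, though they may add to it. Other seed-like sites in these members, and effects through other genes that hold the 7-mer, were not tested. A response to the siRNA or to the loss of its target was not separated by this design, and no biological explanation beyond the group was tested.

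The 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 7772 changed genes and 1257 at least 2-fold by edgeR, the only 1 of the 10 with as many by either count, and the highest of the others gave 0 and 0, with 18 to 159 genes at an unadjusted p under 0.05.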
